A study of Arabidopsis thaliana with 4 samples.

How the data were processed

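Transcript abundance was measured in rosette leaves of Arabidopsis thaliana, ecotype Col-5, on 4 single-colour Affymetrix arrays, 1 for each of a full nutrient solution and solutions without nitrate, phosphate or potassium. Per the labels, seedlings grew on agar medium until day 21, were moved to hydroponics in constant light at 24 °C and 80% humidity, and were harvested 28 h after the nutrient was removed. Total RNA was labelled with biotin, per the labels. The labels list no nitrate salt for the full solution, although they describe the nitrate-free one as lacking calcium nitrate, so the nitrate supply of the reference is uncertain. The solutions differed in more than the missing nutrient. Per the labels, the nitrate-free solution received 4 mM extra calcium sulphate and the phosphate-free solution 0.125 mM extra potassium sulphate. The potassium-free solution lacked both KH2PO4 and KOH and received 0.27 mM extra calcium dihydrogen phosphate, so KH2PO4 was left out of the phosphate-free and the potassium-free solutions alike. Groups were taken from the treatment description of each sample. For the phosphate-depleted sample the letters in the title and in the source name differ, and the written treatment decided.

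The authors deposited 1 table of linear intensity values, with 1 signal per probe set and array. The expression algorithm, its version and its scaling target are not given in the sources used here. The values were never negative, and the mean after trimming 2% of probe sets at each end lay between 100.146 and 100.174 on the arrays, which shows that the deposited intensity values had been scaled to a common trimmed mean. Array background averaged 49.06, 52.89, 51.51 and 52.95 on the full-nutrient, nitrate, phosphate and potassium arrays, and array noise averaged 1.38, 1.43, 1.50 and 1.59, per the labels. The full-nutrient array had 312 masked and 183 outlier cells per the labels, against 0 masked cells on each of the others and 32, 9 and 50 outlier cells.

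Of 8297 probe sets, 50 Affymetrix controls were set aside and 8247 were analysed. The platform annotation named 1 gene for 3794 of these, several for 70 and none for 4383. Entrez identifiers of 3784 of the single-gene probe sets matched the gene table of assembly TAIR10.1, which gave current symbols and locus tags for 3602 genes in all. No gene was named from a probe set with several genes, and no coordinates are given because no genome build belongs to the files.

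Signals were scaled to the common trimmed mean of the arrays (T = 100.16), set to a floor of 0.25 T (25.04) and converted to log2. The log2 ratio of each depleted array to the full-nutrient array is the measure used throughout. A probe set counted as higher or lower from a 2-fold ratio. A ratio with a side at the floor is a bound and is written as at least that many fold. With 1 array per group there is no replicate spread, no test was possible and no p-value is given, so counts and ratios describe these arrays only. The number of arrays limits the precision.

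Since all ratios share the full-nutrient array, arrays without any difference were simulated 100 times. Their noise was drawn, within bins of signal level, from the differences between the nitrate and full-nutrient arrays divided by the square root of 2. These differences contain any effect of nitrate removal and any probe set in which the full-nutrient array stood apart. The simulated noise may therefore be too high for that pair, and the nitrate counts lie near the simulated counts by construction. The noise of the phosphate and potassium arrays was not measured and may be larger. For the overlap of 2 depletions, the most extreme simulated ratios were taken up to the observed list sizes, whether or not they reached 2-fold. This step was added after the result was seen. Known changes were also simulated in a comparison of 8247 probe sets, with the noise described above and only in probe sets with a mean signal above T. Of these, 48.4% of 2-fold, 94.8% of 3-fold and 99.2% of 5-fold higher ones were counted as at least 2-fold higher. A mean of 46.6 unchanged probe sets was counted with them. The shares do not describe dimmer probe sets or arrays with more noise.

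Before the data were examined, 19 gene lists with 468 members were fixed, for nitrate, ammonium, phosphate, potassium, sulphate, starch, photosynthesis, ribosomal proteins, hormones, stress, senescence, the clock, other organs and reference genes. The annotation named 38 of these members. Several probe sets of a gene were averaged. A list with at least 3 measured genes is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on signal level in 20 bins. In unchanged simulated lists of 10 genes, 9.0% had a percentile under 5 or over 95. These lists held random genes with independent noise, so a share near this was set by the design. Genes of a real list may vary together on a single array, which this check does not cover. The rule for naming genes was fixed at the same time. It takes the 10 highest and 10 lowest log2 ratios of each comparison among single-gene probe sets that were at least 2-fold different, above the floor on both arrays and at T or more on the brighter one, then the 5 most extreme of each array alone, up to 4 members of each list, and at most 5 bounds per direction with the brighter array at 2 T or more. Members of the photosynthesis and ribosomal protein lists beyond these 4 are also named, without a mark. Other genes outside this rule were chosen after their values were seen and are marked so. Lists of root-abundant and jasmonate-inducible genes were written after the highest genes of the potassium array had been seen.

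The alternatives tried were quantile normalization, centring on the median ratio, loess centring, floors of 0.1 T and 0.5 T, a pseudocount of 0.25 T in place of the floor, probe sets with the plain ending that stands for a single transcript, a filter at T, the mean of the other 2 depleted arrays or of the other 3 arrays as the reference, the brightest probe set of a gene, random lists without matching, and the mean in place of the list median. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.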

Results

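The series asked which transcripts respond to the loss of a particular major nutrient. Leaf RNA from plants left for 28 h without nitrate, phosphate or potassium was compared with RNA from plants kept on the full solution. The labels list no nitrate salt for that solution, so the nitrate supply of the reference is uncertain in every nitrate ratio. There was 1 array per condition, so no value below has a replicate error and no difference was tested. Between 3921 and 4088 of the 8247 probe sets lay above the floor on each array (47.5% on the full-nutrient and 49.6% on the potassium array). Where 2 or more measured probe sets belonged to the same gene, their log2 ratios spread over a median of 0.27 in nitrate, 0.24 in phosphate and 0.30 in potassium depletion, over 71, 69 and 69 genes.

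The 3 depletions differed in how far leaf transcripts stood from the full-nutrient array. At the 2-fold limit, 35 probe sets were higher and 47 lower after nitrate removal, 153 higher and 59 lower after phosphate removal, and 301 higher and 141 lower after potassium removal. Simulated arrays without a difference gave a mean of about 50 in each direction (50.3 and 51.3 for nitrate, 50.4 and 49.7 for phosphate, 51.6 and 50.4 for potassium). Their noise came from the nitrate and full-nutrient arrays, so the nitrate counts lie near the simulated ones by construction. The noise of the phosphate and potassium arrays was not measured, so counts above the simulated range may partly hold such noise. The highest simulated count was 80 for higher probe sets in phosphate depletion, and 84 for higher and 70 for lower ones in potassium depletion. The 59 lower probe sets of phosphate depletion stayed within the simulated range, which reached 66. Of the higher probe sets, 6, 30 and 92 were bounds, in the order nitrate, phosphate, potassium, because the full-nutrient signal lay at the floor. The counts depended on how low signals were treated. With a floor of 0.1 T they were 100 and 98 for nitrate and 259 and 102 for phosphate, with 226 lower for potassium, and with a pseudocount 19 and 29 for nitrate, with 25 lower for phosphate and 73 lower for potassium.

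**Figure D1:**
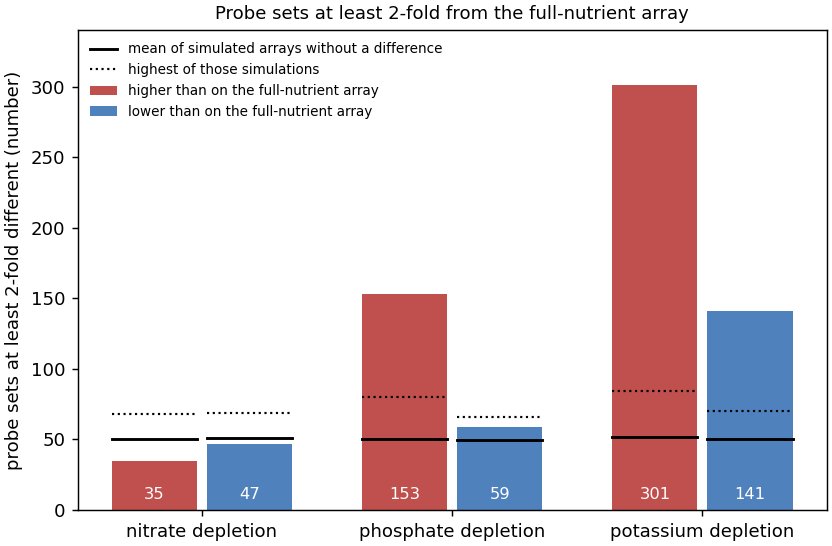
Number of probe sets at least 2-fold higher (red) or lower (blue) than on the full-nutrient array, for each depletion, with the mean (solid line) and the highest value (dotted line) of 100 simulations of arrays without a difference. The potassium bars reach 301 and 141, the nitrate bars 35 and 47.

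Nitrate removal was compared with the full solution first. The lowest named transcripts included those of several enzymes and of a calmodulin-like protein. AT2G43590, a chitinase family gene, had a signal of 926.4 on the full-nutrient and 89.0 on the nitrate array, 10.4-fold lower, and its second probe set was 3.60-fold lower. SAL2, an inositol polyphosphate phosphatase gene, was 5.28-fold lower and CML41, which encodes a calmodulin-like protein, was 5.18-fold lower. AT2G43620, another chitinase family gene, was 2.53-fold lower and AT4G16260, a glycosyl hydrolase family gene, 2.55-fold lower. AT2G16940 (log2 ratio -1.81), the isoflavone reductase-like gene AT1G75280 (-1.70), the copper chaperone gene CCS (-1.43) and AT2G38180 (-1.38) complete the 9 named genes at the lower end.

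Only 2 genes met the naming rule at the upper end in nitrate depletion. COR15B, a cold-regulated gene of a chloroplast protein, had a signal of 284.5 on the full-nutrient and 742.3 on the nitrate array, 2.61-fold higher. AT4G13840, an acyltransferase family gene, was 2.12-fold higher. The highest unnamed probe sets measured on both arrays were 4.58-fold and 2.76-fold higher. CML41, AT2G16940, CCS and AT2G24290 were at least 2-fold brighter on the full-nutrient array than on each depleted array, so their ratios were low in all 3 comparisons. The full-nutrient array stood apart in this way for 9 higher and 3 lower probe sets, a balance that was not stable, since 21 were lower with a floor of 0.1 T, and 2 were higher and 5 lower with a pseudocount.

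Transcripts set apart on the nitrate array alone were more often lower than higher. At the limit of 2-fold from each other array, 13 probe sets were higher and 19 lower, where simulations gave 18.3 and 7.1 on average and at most 34 and 16. The simulated noise was drawn, with random sign, from differences that hold these same probe sets, so the comparison decides nothing on this balance. The lower genes that the naming rule takes were AT2G43590, AT1G75280, AT4G32480, AT4G16260 and AT4G20820. AT4G16260 illustrates the spread between conditions, with signals of 291.8, 114.4, 402.5 and 1204.2 on the full-nutrient, nitrate, phosphate and potassium arrays. These single-array counts were 25 higher and 32 lower with a floor of 0.1 T, and 4 and 12 with a pseudocount. In the comparison with the full solution, 17 probe sets were higher with the floor of 0.5 T and 100 with that of 0.1 T, in place of 35. With the other 3 arrays as the reference, the nitrate array had 55 higher and 135 lower probe sets.

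None of the genes fixed in advance for nitrate uptake and response or for ammonium assimilation (31 and 22 members) was named by the probe annotation used here, so the transcripts closest to the removed nutrient could not be read here. The photosynthesis list, with 7 genes measured, had a median log2 ratio of -0.01 in nitrate depletion, at percentile 45.8 of matched random lists. The 10 cytosolic ribosomal protein genes had a median of -0.03, at percentile 44.5. The list for abscisic acid, cold and drought had a median of 0.43 at percentile 99.3, on 3 genes, COR15B (1.38), KIN2 (0.43) and COR47 (-0.08), and its percentile ranged from 62.0 to 99.8 over the alternatives. The 5 senescence and autophagy genes had a median of 0.00 and the 3 sulphate assimilation genes a median of 0.07.

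In the comparison of phosphate removal with the full solution, higher transcripts outnumbered lower ones. AT4G36850, a PQ-loop repeat family gene, was 5.38-fold higher, AT2G34810, a berberine bridge enzyme-like gene, 4.34-fold, and AT1G09500, an alcohol dehydrogenase-like gene, 4.09-fold. The full-nutrient signals of AT4G36850 (30.4) and AT1G09500 (29.7) lay just above the floor of 25.04, which limits the precision of their ratios. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, was 3.23-fold higher and the osmotin-like gene OSM34 3.18-fold. STZ (ZAT10), a zinc finger gene of stress responses and the single measured member of the touch, wounding and handling list, had log2 ratios of 1.29 and 1.09 on its 2 probe sets. EXO, a gene of brassinosteroid-responsive growth that the naming rule takes in potassium but not in phosphate depletion, was below the floor on the full-nutrient array and at 197.8 on the phosphate array, at least 7.90-fold higher.

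The remaining genes at the upper end of phosphate depletion were AT2G28400 (1.92), TBL37 (1.58), AT4G17790 (1.54), AT4G32480 (1.51) and AT4G26060 (1.48). At the lower end, AT1G76960 had a signal of 1133.4 on the full-nutrient and 196.6 on the phosphate array, 5.77-fold lower, and AT2G16940 was 4.95-fold lower. CML41 was 3.63-fold lower, AT4G27450 3.27-fold, the lectin-domain gene AT3G15356 3.04-fold and AT3G04550, a Rubisco accumulation factor gene, 2.95-fold. AT2G05540 (-1.52), AT1G10690 (-1.35), AT2G44290 (-1.32) and AT3G52070 (-1.30) followed. The highest unnamed probe sets measured on both arrays had log2 ratios of 3.47 and 2.90.

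The measured ribosomal protein genes were lower as a group in phosphate depletion, by small amounts. The list had 40 members, of which the annotation named 10. Of these 10 measured genes 9 were below the full-nutrient array and none reached 2-fold. The median log2 ratio was -0.35, a 1.27-fold lower level, at percentile 0.86 of random lists matched on signal. The 4 most different members were RPL15B (-0.91), RPS3A (-0.61), RPL7C (-0.50) and RPS18B (-0.48), and RPL9B, at 0.13, was the only one above 0. Across the alternatives the median stayed between -0.37 and -0.26 and its percentile between 0.20 and 2.33. The same genes were near the full-nutrient level in potassium depletion (median -0.05, percentile 73.0), and the median of the gene-wise difference between the potassium and phosphate arrays was 0.29, at percentile 99.8 of matched lists.

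Other lists were read in phosphate depletion too. All 7 photosynthesis genes were below the full-nutrient array, with a median of -0.27 at percentile 5.43, and none reached 1.5-fold. This median depended on the scaling, with -0.069 at percentile 41.7 under quantile normalization and -0.088 at percentile 20.1 under loess centring. COR15B was 2.27-fold higher and KIN2 had a gene-level ratio of 0.52, while COR47 had -0.45. The median of this 3-gene list was 0.52 at percentile 99.0 (87.4 to 99.3 over the alternatives). The 5 senescence and autophagy genes had a median of 0.15 and the 3 sulphate genes one of 0.05. None of the 43 phosphate starvation genes fixed in advance was named by that annotation. On the phosphate array alone 19 probe sets were higher and 5 lower, within the simulated range, against 30 and 10 with a floor of 0.1 T and 12 and 3 with a pseudocount. They include AT4G32480, AT5G65687, AT4G17790, the defensin gene LCR68 and AT2G20670 among the higher, and AT2G05540 and AT4G27450 among the lower.

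Potassium removal went with the largest ratios of the series on the higher side, and among named genes the highest were those of an osmotin-like gene and of several enzyme genes. OSM34 had signals of 44.0, 84.4, 139.9 and 1018 on the full-nutrient, nitrate, phosphate and potassium arrays, 23.1-fold higher on the last than on the first. AT1G09500 was 20.6-fold higher, from a full-nutrient signal of 29.7 just above the floor, and its second probe set at least 9.41-fold. BGLU28, a beta-glucosidase gene, was 15.5-fold higher and AT4G17470, a palmitoyl protein thioesterase family gene, 9.36-fold. SAG29 (SWEET15), a sugar transporter gene linked to senescence, was 6.44-fold higher, the aspartyl protease family gene AT1G03220 5.90-fold, and AT4G33150, the gene of the bifunctional enzyme that starts lysine breakdown, 4.69-fold.

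Several further genes lay at the floor on the full-nutrient array and were bright on the potassium array. BGLU21, a beta-glucosidase gene and the single named member of the root marker list, had a signal of 377.2 on the potassium array against 1.7, 0.8 and 5.3 on the full-nutrient, nitrate and phosphate arrays, at least 15.1-fold higher than the floor. The peroxidase gene AT2G38380 was at least 13.9-fold higher, the chitinase gene ChiC at least 9.81-fold and EXO at least 8.21-fold. AT2G37750, AT2G34810 and AT2G28400 were 5.49-, 5.46- and 4.77-fold higher. STZ had log2 ratios of 1.97 and 1.39. The highest unnamed probe set above the floor on both arrays had a signal of 66.6 on the full-nutrient and 2048.0 on the potassium array, 30.7-fold higher.

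At the lower end of potassium depletion, both probe sets of CP5, a gene of a lipid-binding START-domain protein, were lower, 4.47-fold and 3.43-fold. SAL2 was 3.72-fold lower, CML41 3.45-fold, AT2G16940 3.23-fold and AT2G43590 3.20-fold; these 4 genes were also among the lowest after nitrate removal, where the full-nutrient array is the shared reference. AT1G76960 (-1.59), AT3G15356 (-1.58), AT3G52500 (-1.54) and AT1G15260 (-1.49) were the other 4 genes named.

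The measured photosynthesis genes were lower together in potassium depletion. Each of the 7 genes measured was at least 1.5-fold below the full-nutrient array and none reached 2-fold as a gene mean. The median log2 ratio was -0.84, a 1.79-fold lower level, at percentile 0.50 of random lists matched on signal. RCA, which encodes Rubisco activase, had a signal of 5766 on the full-nutrient and 3740 on the potassium array, and LHCB4.1, of the light-harvesting antenna, 7162 and 4220. PSBY (-0.93), PSAN (-0.89), PSBW and PSAE1, subunits of the photosystems, and LHCB4.3 (-0.71) were the other measured genes. The list had 51 members, of which the annotation named 7. The median of the potassium to phosphate difference in these genes was -0.56, at percentile 1.7, and that of the potassium to nitrate difference -0.84, at percentile 0.58. The brightest probe sets as a whole were lower on this array, with a median of -0.18 over 680 probe sets with a mean signal above 401, and the highest signal was 6485 against 11126 on the full-nutrient array. With quantile normalization the list median was -0.42, at percentile 4.21, and with loess centring -0.45, at percentile 2.46.

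**Figure D2:**
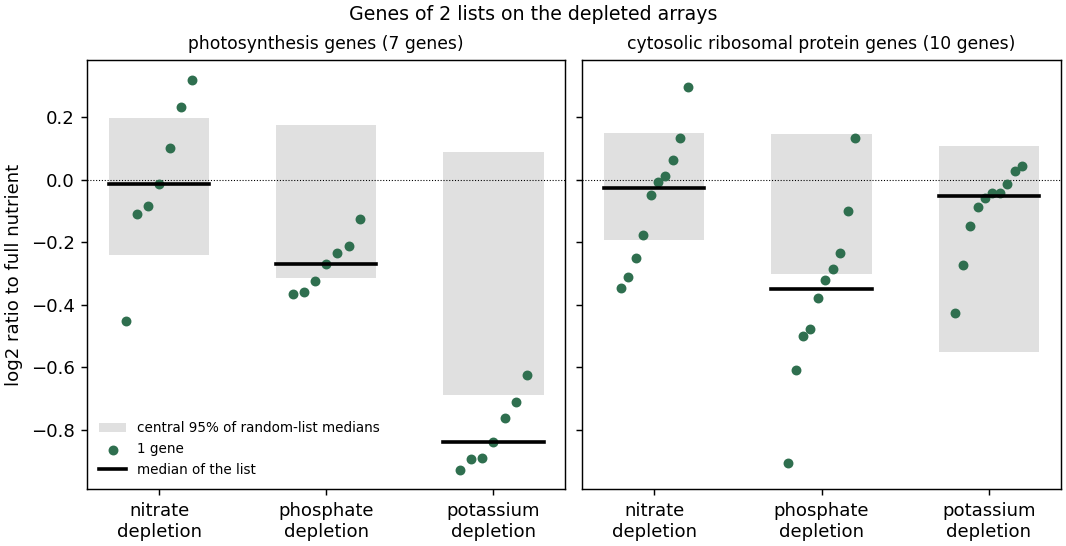
Log2 ratio to the full-nutrient array (vertical axis) of each measured gene of the photosynthesis list (left, 7 genes) and of the cytosolic ribosomal protein list (right, 10 genes) in the 3 depletions. Points are genes, black lines are list medians and grey bands hold the central 95% of medians of random lists; the photosynthesis median in potassium depletion (-0.84) and the ribosomal median in phosphate depletion (-0.35) lie below their bands.

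Among the other lists in potassium depletion, WRKY6, a transcription factor gene of senescence, was 2.89-fold higher and APG8A, of autophagy, 1.65-fold higher, while ATG8E had a log2 ratio of -0.44. The median of these 5 senescence and autophagy genes was 0.33, at percentile 87.5. APL3, a gene of starch synthesis, was at least 2.90-fold higher. The cold and drought list had a median of -0.04, with COR15B at -0.57, and the sulphate list one of 0.00. THI2.1, the single named jasmonate-list gene, had signals of 47.7, 15.3 and 27.4 on its 3 probe sets on the potassium array, and all 3 lay below the floor on the other arrays. The anthocyanin gene DFR was at 33.7 on the potassium array and below the floor on the others, BAN was below the floor on all arrays, and the clock gene GI had a gene-level ratio of -0.10. The flower marker AT5G07230 lay below the floor on each array. No member of the potassium transport list (35 members) was named by the annotation, nor of the salicylate, heat shock and reference gene lists.

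The potassium array held most of the transcripts set apart on a single array. At 2-fold from each of the other arrays, 122 probe sets were higher and 29 lower, where the simulations averaged 18.3 and 7.1 and reached 34 and 16. OSM34, AT4G17470, SAG29, AT1G09500 and AT1G54010 led the higher genes. CP5, AT3G52500, AT4G38690 and the peroxidase gene AT1G71695 led the lower ones. Among probe sets with the plain ending, 74 were higher and 16 lower. The lower ones numbered 45 with a floor of 0.1 T and 15 with a pseudocount.

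Phosphate and potassium removal shared more of their higher transcripts than either shared with nitrate removal. Of the 153 and 301 higher probe sets, 98 were the same, among them EXO, AT1G09500, AT2G34810, AT2G28400, OSM34, GH3.3, TBL37 and STZ. In simulated arrays without an effect, which share a reference too, the 153 and 301 highest probe sets had a mean of 50.4 and at most 62 in common. Not all of these simulated probe sets reached 2-fold. This comparison at equal list size was added after the result was seen. The shared number was 167 with a floor of 0.1 T. For lower probe sets the shared number was 27, within the range of 22 to 41 simulated at equal list size, and it was 41 with a floor of 0.1 T and 9 with a pseudocount. AT1G76960, CML41, AT2G16940, AT3G15356 and AT3G52070 were among the 27. Nitrate and phosphate removal shared 5 higher and 12 lower probe sets, against means of 11.7 and 21.8 simulated at equal list size, and nitrate and potassium removal 9 and 12, against 14.1 and 26.8. With a floor of 0.1 T these numbers were 30 and 21, and 33 and 22. The simulated noise comes from the nitrate and full-nutrient arrays, so a number below its range is not read further.

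Across probe sets, which are not independent replicates, the log2 ratios of phosphate and potassium depletion had a correlation of 0.62 and a covariance of 0.108. Simulated arrays with equal noise and a shared reference gave 0.50 and 0.042, and the 0.50 followed from the equal noise by construction. The difference in covariance was 0.066, which does not measure what the reference array added. Nitrate with phosphate gave 0.23 and a covariance of 0.022, and nitrate with potassium 0.14 and 0.018, both under the simulated covariance. Only 1 full-nutrient array was analysed here, so it could not be split and part of the overlap may stem from it. Between the depleted arrays themselves, 269 probe sets differed at least 2-fold between phosphate and potassium, 284 between nitrate and phosphate, and 557 between nitrate and potassium.

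**Figure D3:**
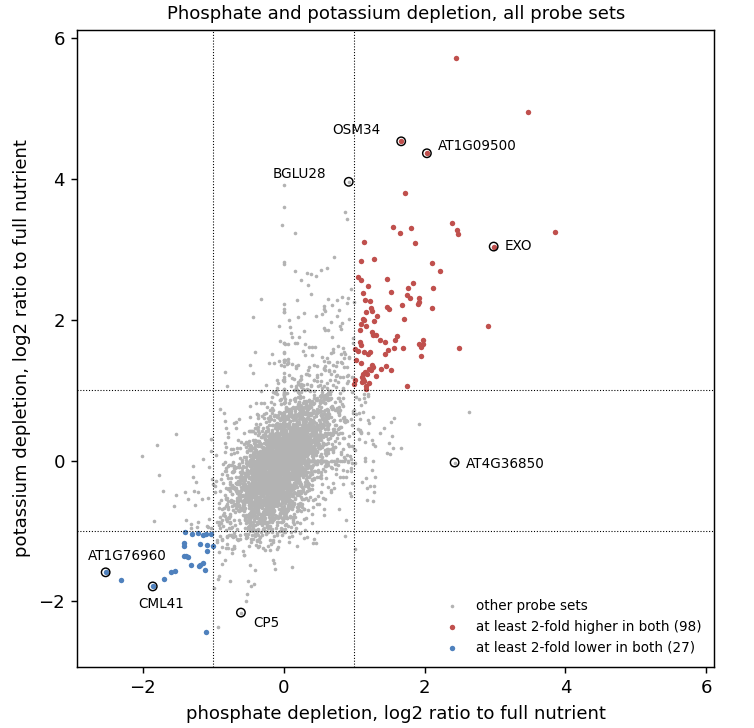
Log2 ratio to the full-nutrient array in phosphate depletion (horizontal axis) and potassium depletion (vertical axis) for each of 8247 probe sets, with dotted lines at the 2-fold limits. Red points (98) are at least 2-fold higher and blue points (27) at least 2-fold lower in both; OSM34 lies at 1.67 and 4.53, and AT4G36850 at 2.43 and -0.03.

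Control probe sets differed between the arrays. The GAPDH 3′ control had a signal of 2064 on the full-nutrient and 2384 on the potassium array, but 401.6 on the nitrate and 475.4 on the phosphate array. The ratio of its 3′ to its 5′ signal was 2.36, 1.46, 1.26 and 2.02 on the full-nutrient, nitrate, phosphate and potassium arrays, and that of ubiquitin 3.16, 3.36, 2.75 and 2.67. The geometric mean of the 9 bacterial spike-in probe sets was 467, 339, 224 and 379.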

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

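The alternatives below were fixed before the data were examined, while the root-abundant and jasmonate-inducible lists, the gene families and the overlap at equal list size were chosen after the data had been seen. Signal over background limits ratios near the floor, and 6, 30 and 92 of the higher probe sets in nitrate, phosphate and potassium depletion were bounds. Quantile, median and loess scaling kept the counts, overlaps and correlations within 1.5 times or their resampling range. The photosynthesis median in potassium depletion moved, to -0.42 with quantile normalization and -0.45 with loess centring. In phosphate depletion it was -0.069 and -0.088 in place of -0.27, a shift inside the range set for a stable value, but its percentile was 41.7 and 20.1 in place of 5.43. In all, 308 of the values that answer a comparison stayed and 77 moved. Of the other values 429 stayed, 115 moved and 12 reversed. Among the ratios of named genes, 19 moved and 38 stayed with a pseudocount, and 13 moved and 44 stayed with a floor of 0.5 T. With a floor of 0.1 T, 4 moved and 53 stayed. Where a value moved the cause was not tested, except that filters leave fewer probe sets and another reference changes the comparison itself.

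With a floor of 0.1 T, counts of higher and lower probe sets were 100 and 98 in nitrate, 259 and 102 in phosphate depletion, and 226 were lower in potassium depletion (main counts 35, 47, 153, 59 and 141). On single arrays, 21 were lower on the full-nutrient array, 25 higher and 32 lower on the nitrate, 30 higher and 10 lower on the phosphate, and 45 lower on the potassium array. Nitrate and phosphate then shared 30 higher and 21 lower probe sets, nitrate and potassium 33 and 22, phosphate and potassium 167 and 41, and all 3 shared 21 higher ones. The correlation of nitrate with phosphate was 0.31 and with potassium 0.21.

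With a floor of 0.5 T, 17 probe sets were higher in nitrate and 38 lower in phosphate depletion. On single arrays 1 was lower on the full-nutrient, 6 higher on the nitrate and 3 lower on the phosphate array. Nitrate shared 2 higher probe sets with phosphate and 3 with potassium, all 3 shared 1, and the correlation of nitrate with phosphate was 0.18. The root-abundant median in phosphate depletion reversed to -0.20.

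With a pseudocount, 19 were higher and 29 lower in nitrate, 25 lower in phosphate and 73 lower in potassium depletion. On single arrays 2 were higher and 5 lower on the full-nutrient, 4 higher and 12 lower on the nitrate, 12 higher and 3 lower on the phosphate, and 15 lower on the potassium array. All 3 depletions shared 5 higher and 2 lower probe sets, and the lower ones shared by nitrate and phosphate, nitrate and potassium, and phosphate and potassium numbered 5, 7 and 9.

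With the plain probe sets (6242), 23 were higher and 27 lower in nitrate, 37 lower in phosphate and 196 higher in potassium depletion. On single arrays 1 was lower on the full-nutrient, 11 lower on the nitrate, and 74 higher and 16 lower on the potassium array. Nitrate shared 2 higher probe sets with phosphate and 5 with potassium, and all 3 shared 1. With the filter at T, 17 were higher in nitrate and 38 lower in phosphate depletion, 6 were higher on the nitrate array alone, and the correlations of phosphate with potassium and with nitrate were 0.66 and 0.16.

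Against the other 2 depleted arrays, 108 were higher and 227 lower on the nitrate and 71 higher on the phosphate array. Photosynthesis medians were 0.50 for nitrate and 0.12 for phosphate, the ribosomal median for nitrate was 0.19 and that of senescence genes -0.37. In phosphate depletion the root-abundant (-0.25) and jasmonate-inducible (-0.13) medians and the ratios of AT1G09500 (-0.25), OSM34 (-1.07) and CML41 (0.22) reversed, as did AT2G16940 in nitrate (0.19) and CML41 (0.33), AT2G16940 (0.37) and AT2G43590 (0.48) in potassium depletion. Against the other 3 arrays, 55 were higher and 135 lower on the nitrate, 75 higher and 37 lower on the phosphate array. The photosynthesis medians were 0.33 and -0.012, that of senescence genes for nitrate -0.35, and in phosphate depletion the root-abundant median (-0.051) and OSM34 (-0.16) reversed.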

Other observations

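The jasmonate-inducible and root-abundant lists, the gene families and all tests of explanations in this part were chosen only after the results were seen, except the test of signal brightness, which was written before but whose random-list comparison, bootstrap interval and drawing error were added after. Of 36 genes listed as induced by jasmonate, a hormone of wounding and defence, 4 were named, and all 4 were at least 1.5-fold above the full-nutrient array in potassium depletion. Of these, 2 lay below the floor on the full-nutrient array and were measured because they were high on the potassium array, so the list median of 1.10 (0.94 to 1.56 over the alternatives) is partly selected by the outcome and says little about the list as a whole. JOX4, whose enzyme inactivates jasmonate, had signals of 1.5, 8.8, 53.8 and 96.1 on the full-nutrient, nitrate, phosphate and potassium arrays. AT4G24350, of the vegetative storage protein family, had log2 ratios of 0.95 and 1.50 on its 2 probe sets in potassium depletion. In phosphate depletion 3 genes were measured, 1 of them below the floor on the full-nutrient array, with a median of 0.60. Over the alternatives that median ran from -0.13 to 0.63, and its direction reversed against the other 2 depleted arrays. In nitrate depletion 2 genes were measured, with a median of -0.04.

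Some genes known for high expression in roots stood apart on the potassium array of these leaf samples. Of 17 named genes 7 were measured, and 5 of these were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.84. Of the 7, 4 were below the floor on the full-nutrient array and entered because they were high on the potassium array, so the median rests partly on bounds. With a floor of 0.1 T it was 0.92 over 13 genes, and over the alternatives it ran from 0.84 to 1.90. AT4G12545, a lipid transfer protein family gene, had a signal of 4.2 on the full-nutrient and 149.1 on the potassium array, and the peroxidase gene AT5G64100 10.0 and 98.0. AT4G11290, another peroxidase gene of the list, was at least 2.82-fold lower. In phosphate depletion the list median was 0.30 over 9 genes, 6 of them below the floor on the full-nutrient array. It ran from -0.25 to 0.89 over the alternatives, so its direction is not settled. In nitrate depletion it was -0.02 over 3 genes, and -0.78 over 9 genes against the other 2 depleted arrays.

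Some ATG8 genes, which encode the ubiquitin-like proteins of autophagosomes, were higher by small amounts in nitrate and in potassium depletion. A search of gene symbols gave 6 families with at least 4 measured genes, each examined in the 3 depletions. The 5 genes with ATG symbols had a median of 0.51 in nitrate depletion, at percentile 99.6, and between 0.47 and 0.49 under the 3 other scalings. ATG8E had a signal of 697.4 on the full-nutrient and 1031.1 on the nitrate array, and ATG8F 820.1 and 1171.3. ATG8C had a log2 ratio of 0.52, ATG8B 0.13 and ATG8D 0.00, and none of the 5 genes reached 2-fold. APG8A, the same kind of gene under another symbol, had -0.12, and with it the median of 6 genes was 0.32 at percentile 99.0. The median of the 6 genes was 0.15 in phosphate depletion, at percentile 85.9, and 0.33 in potassium depletion, at percentile 96.5. With the main scaling the 6-gene median was thus no higher in nitrate than in potassium depletion. The 5-gene median in potassium depletion was 0.33 at percentile 95.8. Under quantile normalization it was 0.20 at percentile 86.2, against 0.47 at percentile 99.5 in nitrate depletion.

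Phosphate and potassium removal shared 98 higher probe sets. If the shared full-nutrient array were the cause, all pairs of depletions would have a like covariance. That of phosphate with potassium was 4.98 times the larger of the other pairs, which argues against that array as the whole cause. The bootstrap interval of 4.16 to 6.06 covers the sampling of probe sets only, not variation between arrays or plants. For a shared hybridisation difference the spike-in controls gave no decision: their mean was 0.76 higher (log2) on the potassium than on the phosphate array, and these arrays did not lie together on the same side of the others. Day, batch and plant position are not given in the sources used here and stay open. A response to the nutrients is open too and was not tested. KH2PO4 was absent from both solutions. Per the labels, however, calcium dihydrogen phosphate was added to the potassium-free solution and potassium sulphate to the phosphate-free one. By these labels neither solution lacked both potassium and phosphate.

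The measured photosynthesis genes were lower in potassium depletion and most of them are bright, but LHCB4.3, with 172.5 on the full-nutrient array, was 1.64-fold lower too. If compression of bright signals were the cause, other genes of that brightness would be lower by at least 0.5 of the list median, which is -0.42; the 482 other genes within the list's range of signal had a median of -0.044, which goes against it, but LHCB4.3 stretches that range to dimmer genes, and matched random lists had -0.20 and the 11 brightest other genes -0.38 (bootstrap interval -0.65 to -0.16). After loess centring the list lay at percentile 2.46 against a bound of 2.5 set before, closer than the drawing error of 0.16; the values without these margins met the bounds first written against compression, and with them compression cannot be told apart from an effect on these genes. Root RNA in the sample may also lower leaf transcripts. A share of 44.1% would be needed if root RNA held no photosynthesis transcripts and explained the whole median of -0.84. The share would be smaller if part of the drop were compression. The 17 root-abundant genes had a median signal of 18.9 on the potassium and 4.2 on the full-nutrient array, both under the floor. Of the 7 measured, 5 were at least 2-fold higher and 1 at least 2-fold lower. BGLU21, of the root marker list fixed in advance, was at 377.2 against 1.7. AT2G37130 was at 408.0 against 487.0 and AT1G54010 at 386.3 against 103.3. However, 3 of the 17 were above the floor on the full-nutrient array too, and without a root array their level in root RNA is unknown. An effect of potassium removal on these genes stays among the open explanations, untested.

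Some genes, such as CML41, AT2G16940 and CCS, were low in all depletions, and in these the full-nutrient array stood apart. The number of such probe sets was 12 in both directions, and the simulated noise was drawn from differences that hold these same probe sets, so its comparison with this count decides nothing on the noise of single arrays. Masked cells on the full-nutrient array are a further candidate cause, since the 312 cells equal 9.08 whole probe sets, but their positions were not used here and this stays open too. A response common to the 3 removals is open and was not tested.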
